A study of Mus musculus with 2 samples.

How the data were processed

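Striatal RNA of male mice aged 6 months was measured on Affymetrix MOE-430A arrays, which carry sets of short oligonucleotide probes for mouse transcripts. Per the labels' protocols, total RNA was extracted with Trizol and cleaned on columns, and the RNA of 6 mice of each genotype was combined into 1 pool. Each pool was labelled with biotin and hybridised to 1 array. The transgenic mice carried human wild-type alpha-synuclein (SNCA) under the Thy-1 promoter, and the controls were wild-type littermates on the same mixed C57BL/6 and DBA background.

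The deposited values are signal intensities on a linear scale, computed by the authors with the MAS 5.0 software per the labels and the series' design text. MAS 5.0 combines the probes of a set, with their mismatch probes, into 1 signal. The mean signal, with 2% of the values trimmed at each end, was 2501 on both arrays, as it would be after scaling to a common level, although the scaling target is not given in the sources used here. No detection calls or change p-values of that software were used here. Arrays give no counts, so depth has no meaning here, and the number of arrays limits the precision.

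Of 22690 probe sets, 20393 were paired with 1 gene symbol and 691 with several in the platform annotation used here. The other 1606 were not listed in it, 51 of them control probe sets, and these were not named. By gene ID, 20364 of the probe sets with 1 symbol were found in a mouse reference gene table, which changed 0 symbols. No probe set was named as Snca in that annotation, so the overexpressed gene was not analysed here and the genotype labels were not checked against it. No genome build belongs to the array values, so no coordinates are given.

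The log2 ratio of the transgenic over the wild-type signal was computed per probe set with no pseudocount. Probe sets were kept where the mean signal of both arrays was at or above the 50th percentile, a signal of 1074, which left 11345 probe sets. A size threshold of 0.6 on the log2 scale, 1.52-fold, was taken from the series' design text, and probe sets past it were counted in each direction. Without detection calls, the filter on the mean signal stood in for the exclusion of absent probe sets. A gene was represented by its brightest probe set, provided that this passed the filter, which gave 7018 genes.

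With 1 array per genotype there was no replicate and no test, and no p-value is reported. The only error that could be estimated came from genes with at least 2 probe sets past the filter. Their pooled within-gene SD of the log2 ratio was 0.29 over 2364 genes. It covers measurement error and transcript variants, not variation between mice, labelling reactions or arrays. An SD given beside a gene is the SD over its probe sets, with n the number of probe sets.

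The 35 gene lists, with 1195 distinct genes, were written before the data were examined, as were the filter, the size threshold, the rule for named genes and all alternatives except 1. For the 30 lists with at least 5 measured genes, the list median was placed among the medians of 10000 random lists of the same size, matched on mean log2 signal in 10 bins. A median below the 2.5th or above the 97.5th percentile is said to stand apart. This describes these 2 arrays only, since genes are not replicates. About 1.5 of the 30 lists would stand apart by chance if genes varied independently. The procedure was tested on simulated data over 7018 genes for the same comparison. With no true shift, 6% of the simulated lists of 12 genes and 6% of those of 30 genes stood apart. Simulated members were drawn at random, so this rate need not hold for lists whose genes vary together. A true shift of 0.2 was found in 64% of the lists of 12 genes and in 97% of the lists of 30 genes.

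The genes named were fixed by rule. They were the 10 highest and 10 lowest genes by log2 ratio, and the 8 highest and 8 lowest genes among those with several probe sets in 1 direction, ranked by the smallest ratio. They also included up to 4 members of each list with the largest ratio in size, the brightest members of lists of a cell type or tissue part, the sex-linked and strain-variable genes, and the control probe sets. Other genes are named only where the text says that they were chosen after their values were seen.

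The alternatives were centring on the median log2 ratio, intensity-dependent centring (loess, span 0.4), quantile normalization, a pseudocount at the 20th percentile of all signals (252), no filter, and a filter at the 75th percentile (3069). Further alternatives were a size threshold of 1.0, the omission of probe sets of the _s_at, _x_at and _a_at classes, which may match several transcripts, and the mean of a gene's probe sets. The omission of genes held by several lists was added after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.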

Results

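The comparison addressed which striatal transcripts differ between mice that overexpress human wild-type alpha-synuclein and their wild-type littermates. Alpha-synuclein is a presynaptic protein that accumulates in Parkinson disease. The striatum is the main target of the dopamine neurons that are lost in that disease. There were 2 groups, each measured on 1 array with RNA pooled from 6 male mice aged 6 months. The arrays held 22690 probe sets each. The median signal was 1072 in the transgenic pool and 1080 in the wild-type pool, and the largest signals were 161913 and 150228. There was no replicate of either pool, so all differences below are differences between 2 arrays.

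The pools had similar profiles, and the differences were about equal in both directions. Both arrays had the same trimmed mean signal of 2501. A common scale can itself bring the directions near balance, so that balance says little about the pools. Over the 11345 probe sets past the signal filter, the log2 signals of the pools correlated across probe sets with Pearson's r = 0.97, and probe sets are not independent replicates. The median log2 ratio was 0.0053 and the SD of the log2 ratio was 0.33. A log2 ratio of at least 0.6 was reached by 361 probe sets in the direction of higher transgenic signal and by 371 in the other. Together they were 6.45% of the probe sets past the filter. The within-gene SD of 0.29 was nearly as large as the SD over these probe sets, so this count cannot be read as a count of genotype differences. At a size of 1.0 there were 59 higher and 54 lower probe sets. Counted as genes, 188 were higher and 220 lower at 0.6 among 7018.

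Different probe sets of the same gene often disagreed. In 117 genes the brightest probe set passed 0.6 in size and a second one passed the filter. The second had the same direction in 78 of them (66.7%), and it also passed 0.6 in 21 (17.9%). Over all 2364 genes with at least 2 such probe sets, 55.8% shared the direction, little more than an even split. The log2 ratios of the brightest and the second probe set correlated with Pearson's r = 0.23 over these genes. With these probe sets split into 3 equal groups by signal, the within-gene SD of the log2 ratio was 0.33 in the dimmest group and 0.24 in the brightest.

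**Figure D1:**
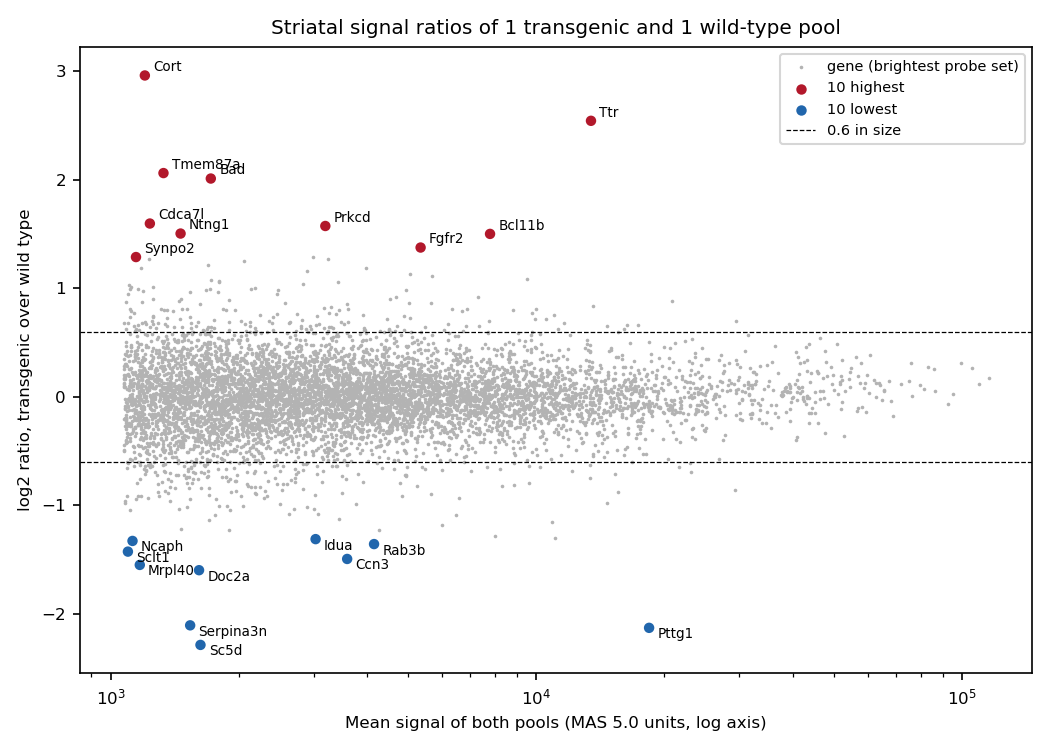
The log2 ratio of transgenic over wild-type signal (vertical axis) is plotted against the mean signal of both pools (horizontal log axis, MAS 5.0 units) for 7018 genes, with the 10 highest genes in red, the 10 lowest in blue and dashed lines at 0.6 in size. Ttr at 2.54 and Pttg1 at -2.13 stand far from other genes of similar brightness, while most of the other extreme genes lie at low signal.

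The genes with the highest ratios included a neuropeptide, a thyroid hormone carrier and a transcription factor of striatal projection neurons. Cort (probe set 1449820_at), which encodes the interneuron peptide cortistatin, had a signal of 2134 in the transgenic pool and a dim 274 in the wild-type pool. Its log2 ratio of 2.96, on a single probe set, was the largest with no pseudocount, but with a pseudocount of 252 it was 2.18, below the 2.47 of Ttr. Ttr, which encodes transthyretin and is made in the brain mainly by the choroid plexus, was higher on each of its probe sets, with a log2 ratio of 2.62 ± 0.15 (SD, n = 3 probe sets). On its brightest probe set (1454608_x_at) the signal was 22948 against 3942, a 5.82-fold difference. Bcl11b (1450339_a_at), a transcription factor of striatal projection neurons, had signals of 11508 and 4069, a 2.83-fold difference. Fgfr2, a fibroblast growth factor receptor, had a log2 ratio of 1.00 ± 0.52 (SD, n = 2 probe sets). Prkcd, protein kinase C delta, was 2.97-fold higher on its single probe set, and Ntng1, the axon guidance protein netrin-G1, had a log2 ratio of 0.94 ± 0.80 (SD, n = 2 probe sets). Tmem87a, Cdca7l and Synpo2 had log2 ratios of 2.06, 1.60 and 1.29. The wild-type signals of these 3 genes, of Bad (684) and of Ntng1 (762) were under 1074. Bad, which promotes apoptosis, had a log2 ratio of 2.01 on its brightest probe set, and 0.28 on a dimmer one that did not pass the filter.

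The genes with the lowest ratios included a cell cycle regulator, a protease inhibitor and proteins of vesicle release. Pttg1, which encodes securin, an inhibitor of chromatid separation, had a signal of 6856 in the transgenic and 29963 in the wild-type pool on its brightest probe set (1438390_s_at), 4.37-fold lower. Its log2 ratio over probe sets past the filter was -1.42 ± 1.00 (SD, n = 2 probe sets). Serpina3n (1419100_at), a protease inhibitor made by reactive astrocytes, had signals of 580 and 2496, 4.30-fold lower. Ccn3, a secreted matricellular protein, had a log2 ratio of -1.69 ± 0.27 (SD, n = 2 probe sets). Doc2a, a calcium sensor of vesicle release, and Rab3b, a vesicle GTPase, had log2 ratios of -1.60 and -1.36 on single probe sets, with a transgenic signal of 802 for Doc2a. Idua, a lysosomal enzyme, had a log2 ratio of -0.98 ± 0.47 (SD, n = 2 probe sets). Mrpl40, Sclt1 and Ncaph had log2 ratios of -1.55, -1.43 and -1.33 with transgenic signals under 1074, and a dimmer Ncaph probe set gave -0.043. Sc5d, an enzyme of cholesterol synthesis, had the lowest ratio with no pseudocount, -2.28 from a transgenic signal of 554, while its dimmer probe set gave 0.70. With a pseudocount of 252 Sc5d was at -1.87, and Pttg1 was lowest at -2.09.

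A set of 16 genes had the largest differences that all their probe sets past the filter shared. On the higher side, beside Ttr and Fgfr2, these were Patj (0.84 ± 0.16), a cell polarity protein, Tgfa (0.74 ± 0.03), a ligand of the epidermal growth factor receptor, and Cdk5r2 (1.00 ± 0.45), an activator of the kinase Cdk5. Septin4 (0.70 ± 0.06), Map3k3 (0.68 ± 0.03) and the phosphodiesterase Pde7b (0.77 ± 0.23) completed that side. On the lower side, beside Pttg1, Ccn3 and Idua, the synaptic proteins Stx1a (-0.68 ± 0.09) and Syn2 (-0.614 ± 0.002) were lower, as were Mfsd4a (-0.68 ± 0.02), Jpt1 (-0.80 ± 0.24) and Cap1 (-0.76 ± 0.25). Values are mean log2 ratios with the SD over n = 2 probe sets. These genes were selected for probe sets that shared a direction, so that agreement is no separate support.

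**Figure D2:**
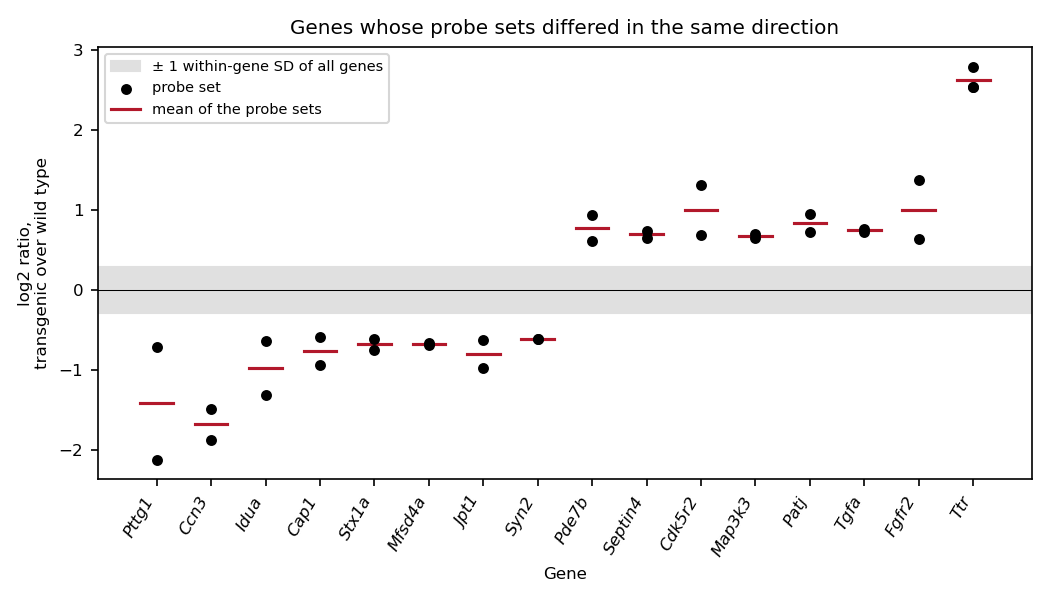
Each point is the log2 ratio (vertical axis) of 1 probe set past the filter for the 16 genes named along the horizontal axis, red lines are the means, and the grey band is ± 1 within-gene SD (0.29) of all genes with several probe sets. These genes were chosen for the size of their smallest ratio, so all points lie outside the band by selection. The Ttr points between 2.53 and 2.79 are the farthest from 0.

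Of the 30 gene lists with enough measured genes, 4 stood apart on the higher and 4 on the lower side. About 1.5 in all would do so by chance if genes varied independently, which the genes of a list need not do. Genes of striatal projection neurons were higher in the transgenic pool as a group. Of 30 measured genes, 25 had a higher and 5 a lower signal, 8 of them at least 0.6 higher and 0 at least 0.6 lower. The median log2 ratio was 0.43, 1.35-fold, above the medians of all 10000 random lists, whose central range ended at 0.10. Beside Bcl11b, the members with the largest ratios were Ido1 (1.06), Rasgrp2 (0.81), an exchange factor for small GTPases, and Rasd2 (0.70), the striatal GTPase Rhes. The 3 Rasgrp2 probe sets past the filter had a mean of 0.41 ± 0.36 (SD). The brightest members were Pcp4 (0.31), Penk, the enkephalin precursor (0.49), and Arpp19 (0.28). Drd2, the dopamine D2 receptor, was at 0.60, Ppp1r1b, the dopamine-regulated phosphatase inhibitor DARPP-32, at 0.51 and Tac1, the substance P precursor, at 0.45, and these 3 were named after their values were seen. Myelin genes were also higher and genes of cortical neurons lower in the same pool, with medians of 0.26 and -0.16. The list of striatal interneurons had a median of 0.22 over 11 genes, at the 98.9th percentile, with 7 higher and 4 lower. Its members had different directions. Cort was at 2.96 and Slc18a3, the vesicular acetylcholine transporter, at 0.58, while Vip and Lhx6 were at -0.87 and -0.62. The bright interneuron peptides Sst and Npy were at 0.25 and 0.28, and the channel gene Kcnc1 was at -0.20.

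The lists of neurons outside the striatum had lower medians under the main settings, though not under all alternatives. Each of these lists had members in both directions. The cortex and hippocampus list had a median of -0.16 over 20 genes, at the 0.640th percentile, with 13 lower, and its members Ccn3 (-1.49), Stx1a (-0.75), Nr2f1 (-0.69) and Mef2c (-0.51) had the largest ratios. Nrgn, the brightest member, was at 0.085. Without the 3 genes that other lists also hold, the cortex and hippocampus median was -0.042, at the 26.1st percentile. Without _s_at, _x_at and _a_at probe sets it was -0.14 and no longer stood apart either. Its lowest value over the alternatives was -0.30. The list for thalamus, pallidum, septum and hypothalamus had a median of -0.24 over 19 genes, at the 0.145th percentile, and its members had both directions. The hypothalamic peptide genes Avp (vasopressin) and Hcrt (hypocretin) were at -1.30 and -1.03, the latter named after its value was seen, and Oxt was at -0.24. Prkcd, Synpo2 and Ramp3 were at 1.57, 1.29 and 1.19. Of the 19 genes, 3 were at least 0.6 higher and 5 at least 0.6 lower. The list combines several tissue parts, so its median describes none of them alone. This list did not stand apart with no filter (-0.016) or with a filter at the 75th percentile (0.10). In the choroid plexus and ependyma list, 4 genes passed the filter, with Ttr at 2.54, Folr1 at 0.32, Igf2 at -0.13 and Igfbp2 at -0.84.

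**Figure D3:**
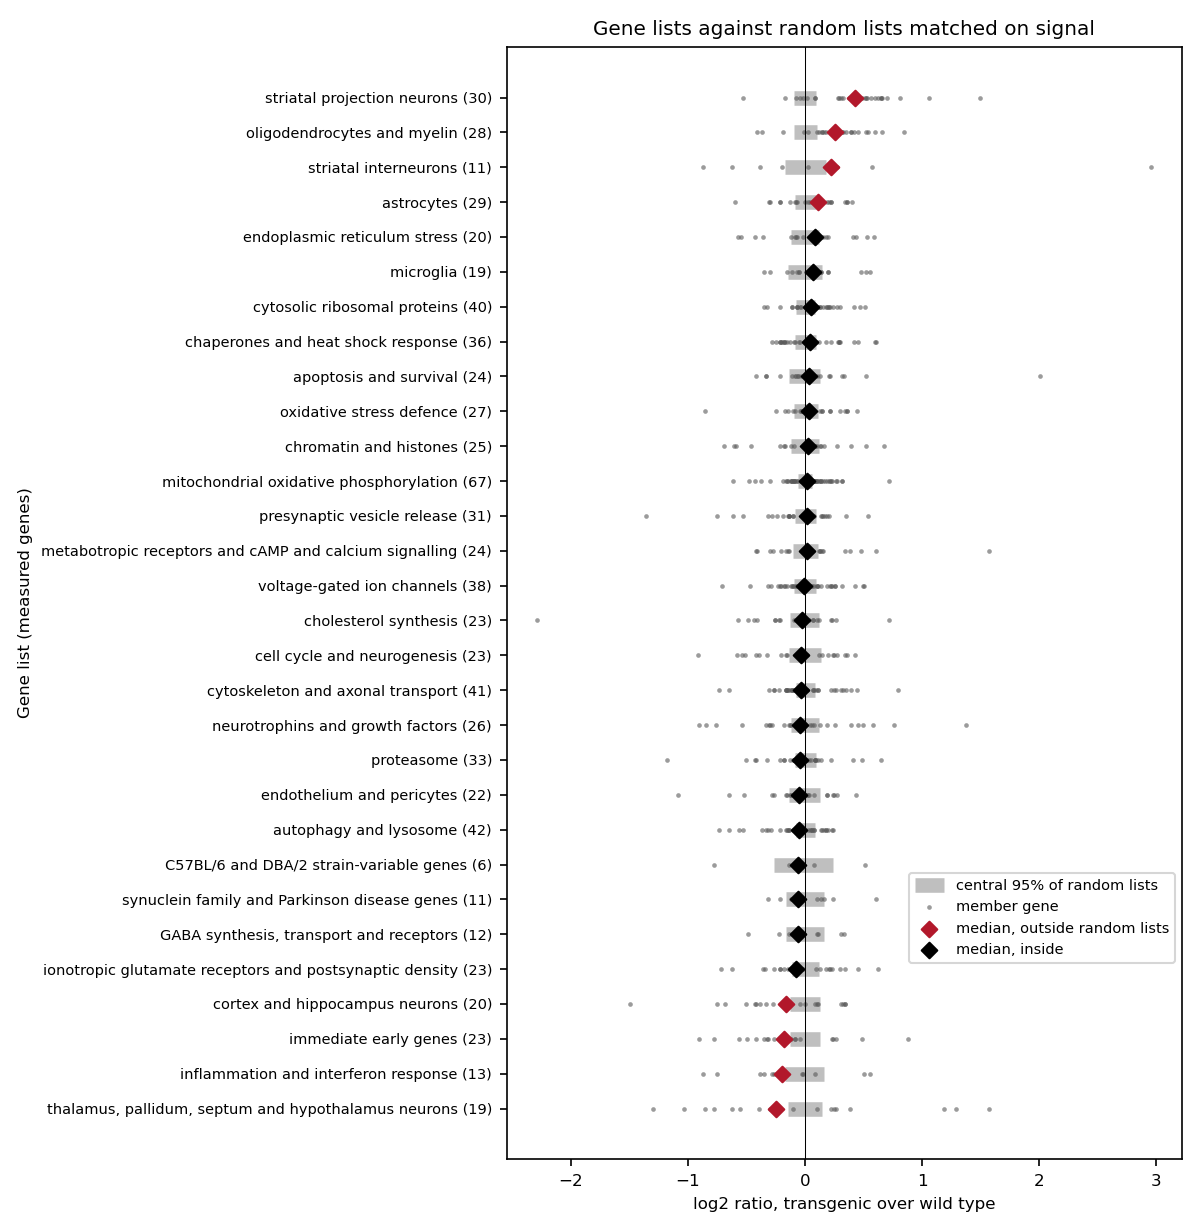
The log2 ratios (horizontal axis) of the measured members of 30 gene lists (rows, number of genes in parentheses) are shown as dots, list medians as diamonds, and the central 95% of medians of matched random lists as grey bars. The medians of striatal projection neurons (0.43) and of oligodendrocytes and myelin (0.26) lie farthest outside the bars on the higher side.

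Myelin genes were higher in the transgenic pool, and other glial and vascular lists differed less. The list of oligodendrocytes and myelin had 24 of 28 genes higher, with a median of 0.26, 1.20-fold, above all random lists. Olig2, a transcription factor of the lineage, was at 0.85, Septin4 at 0.65, Cryab at 0.60 and Gpr37 at 0.54. The brightest members were Mbp (0.14), Cnp (0.32) and Ptgds (-0.37), the last of which is also made in the meninges and was at -0.058 on a second probe set. The 8 Mbp probe sets past the filter lay between -0.24 and 0.81. A dimmer Cryab probe set that passed the filter gave -0.071. Astrocyte genes had a median of 0.11 over 29 genes, at the 98.7th percentile, with none past 0.6. Among them Slc1a3, a glutamate transporter, was at -0.60 and on other probe sets between -0.70 and 0.018, Mlc1 at 0.41, Mt2 at 0.36 and Gpr37l1 at 0.36, and the bright genes Cst3, Apoe and Aldoc were at 0.11, 0.00 and 0.23. The astrocyte median did not stand apart in 4 of 9 alternatives, which were quantile normalization (0.060), the omission of _s_at, _x_at and _a_at probe sets (0.059), the mean of probe sets (0.067) and the omission of genes that other lists hold (0.10). Microglial genes had a median of 0.066 over 19 genes (12 higher, 7 lower), at the 80.1st percentile, with Csf1r at -0.11, Fcrls at 0.56 and the complement genes C1qc and C1qa at 0.52 and 0.20. The 3 Csf1r probe sets past the filter lay between -0.16 and 0.38. Endothelial and pericyte genes had a median of -0.048 over 22 genes (10 higher, 12 lower), at the 24th percentile. Mgp, Acta2 and Col4a2 were at -1.08, -0.65 and -0.52, and Flt1 was at 0.43, with a second probe set at 0.081. Of the blood cell list, Lyz2 alone passed the filter, at 0.080.

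Genes of vesicle release had no common direction. Of 31 measured genes, 17 were higher and 14 lower, the median was 0.015, at the 56.4th percentile, and 3 passed 0.6 in size, all lower. These were Rab3b (-1.36), Stx1a (-0.75), a membrane fusion protein, and Syn2 (-0.61), which tethers vesicles, and Rph3a was at 0.54. The list of ionotropic glutamate receptors and the postsynaptic density had a median of -0.076 over 23 genes (10 higher, 13 lower), at the 9.06th percentile. Homer2, a scaffold protein, and Cacng2, the auxiliary AMPA receptor protein stargazin, were at -0.72 and -0.63. The kainate receptor gene Grik5 and Shank3 were at 0.62 and 0.45. Metabotropic, cAMP and calcium signalling genes had a median of 0.015 over 24 genes (12 higher, 12 lower), at the 57th percentile, with Prkcd at 1.57, Camk4 at 0.61, Plcb4 at 0.48 and Prkca at -0.41. Genes of GABA synthesis, transport and receptors had a median of -0.062 over 12 genes (4 higher, 8 lower), at the 20.8th percentile, and none passed 0.6. Their largest ratios were those of Gabrg1 (-0.48), Gabrd (0.33), Gad2 (0.31) and Abat (-0.22). Voltage-gated ion channels had 19 genes in each direction and a median of -0.0074, at the 42.2nd percentile, with Cacnb4 at -0.71, Kcna1 at 0.51, Kcnab1 at 0.49 and Cacna2d1 at -0.47. Of the dopaminergic neuron markers, Th, tyrosine hydroxylase, was at 0.16, Ddc at -0.35, Nr4a2 at -0.58 and Aldh1a1 at 0.37. Of the serotonin and noradrenaline markers, Htr3a was at -0.70, Htr1b at 0.42, Htr2c at 0.15 and Htr1a at 0.033.

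Activity-regulated and inflammatory genes were lower as groups by their list medians. In the same pool the cell type lists also differed, with medians of -0.16 for cortex and hippocampus neurons, 0.43 for striatal projection neurons and 0.26 for oligodendrocytes and myelin. Of 23 immediate early genes, 18 were lower, with a median of -0.18, at the 0.290th percentile. Bdnf, a neurotrophin induced by activity, was at -0.90, Gadd45b at -0.77 and Ppp1r15a at -0.56, while Nptx2 was at 0.88. With a filter at the 75th percentile, 11 of these genes remained and the median of -0.089 no longer stood apart. Of 13 genes of inflammation and the interferon response, 10 were lower, with a median of -0.20, at the 1.23rd percentile. B2m, the light chain of class I histocompatibility molecules, was at -0.64 ± 0.33 (SD, n = 2 probe sets) and Cd74 was at -0.75, while Rela and Vcam1 were at 0.56 and 0.51. That median did not stand apart in 3 alternatives, and was -0.094 as the mean of probe sets.

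Lists tied to protein quality control, mitochondria and cell death did not stand apart. Oxidative phosphorylation had a median of 0.016 over 67 genes (37 higher, 30 lower), at the 55.6th percentile, with Ndufa5 at 0.71, Ndufb8 at -0.61, Ndufa12 at -0.48 and Uqcr10 at -0.43. A second Ndufa5 probe set gave -0.011, and the probe set means of Ndufa12 and Uqcr10 were -0.24 and -0.23 (n = 3 probe sets each). The proteasome list had a median of -0.046 over 33 genes (15 higher, 18 lower), at the 13.5th percentile, with Psmb6, a catalytic subunit, at -1.18, Psme3 at 0.65, Psmd11 at -0.50 and Psmb1 at 0.49. Other probe sets gave -0.25 for Psme3 and up to 0.22 for Psmd11. Chaperones had a median of 0.044 over 36 genes (20 higher, 16 lower), at the 79th percentile, with Hspa4 (0.61), Cryab (0.60), Stip1 (0.46) and Hspa8 (0.42) highest, each on the brightest probe set. Over all probe sets past the filter the means were smaller, 0.28 ± 0.29 for Hspa4 and 0.15 ± 0.24 for Hspa8 (SD, n = 3 probe sets each) and 0.26 ± 0.47 for Cryab (SD, n = 2 probe sets). The endoplasmic reticulum stress list had a median of 0.088 over 20 genes (11 higher, 9 lower), at the 91.3rd percentile, with Dnajb11 at 0.59, Ddit3 at 0.53, Herpud1 at -0.54 and Hyou1 at -0.57, and second probe sets gave 0.58 for Hyou1 and -0.033 for Herpud1. Oxidative stress defence had a median of 0.031 over 27 genes (16 higher, 11 lower), at the 65th percentile, with Gpx3 at -0.85, Gpx1 at 0.44, Srxn1 at 0.36 and Mt2 at 0.36, while other Srxn1 probe sets gave 0.051 and -0.12. Autophagy and lysosome genes had a median of -0.049 over 42 genes (15 higher, 27 lower), at the 10.4th percentile, with Atg7 at -0.74, Atp6v1a at -0.65, Npc1 at -0.57 and Atg16l1 at -0.53, and a second Atp6v1a probe set gave -0.21. The apoptosis list had a median of 0.033 over 24 genes (14 higher, 10 lower), at the 70.9th percentile, with Bad at 2.01, Cdkn1a at 0.52, Bnip3 at -0.42 and Casp2 at -0.33. Among 11 measured genes of the synuclein family and Parkinson disease (5 higher, 6 lower), the median was -0.058, at the 25.8th percentile. Lrrk2 was at 0.61, Sncb, beta-synuclein, at 0.24, Vps35 at -0.32 and Dnajc13 at -0.22, and a second Vps35 probe set gave -0.0058.

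The remaining lists also lay inside the range of random lists under the main settings. Cell cycle and neurogenesis genes had a median of -0.032 over 23 genes (11 higher, 12 lower), at the 31.3rd percentile, with Hes1, Id2, Cdkn2c and Dcx at -0.91, -0.58, -0.54 and -0.51, and another Dcx probe set at 0.00. That median stood apart with no filter (-0.17) and with a filter at the 75th percentile (-0.20). Neurotrophins and growth factors had a median of -0.046 over 26 genes (12 higher, 14 lower), at the 21.1st percentile, with Fgfr2 at 1.37, Bdnf at -0.90, Igfbp2 at -0.84 and Tgfa at 0.76. Cytoskeleton and axonal transport genes had a median of -0.033 over 41 genes (17 higher, 24 lower), at the 16.2nd percentile, with the neurofilament genes Nefm and Nefl at 0.79 and 0.45 and the kinesin genes Kif5c and Kif5a at -0.73 and -0.65. A second Kif5c probe set gave 0.090. Chromatin genes had a median of 0.029 over 25 genes (14 higher, 11 lower), at the 66.3rd percentile, with Kdm5c, Hdac2, Hdac1 and Suz12 at -0.69, 0.68, -0.61 and -0.59, and other Suz12 probe sets past the filter gave 0.21 and 0.55. Cholesterol synthesis genes had a median of -0.026 over 23 genes (9 higher, 14 lower), at the 31.7th percentile. Sc5d was at -2.28, Hmgcs1 at -0.57, with other probe sets up to 0.075, and Msmo1 at -0.49, while Srebf2, a regulator of the pathway, was at 0.65 ± 0.10 (SD, n = 2 probe sets). Cytosolic ribosomal protein genes had a median of 0.050 over 40 genes (29 higher, 11 lower), at the 80.6th percentile, with Rpl37, Rps10, Rps2 and Rplp0 at 0.52, 0.47, 0.42 and -0.35, and other Rps10 probe sets between -0.17 and 0.15. As the mean of probe sets, the ribosomal median was 0.095 and stood apart.

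Control probe sets described the RNA and the arrays. The 3' over 5' signal ratio of Actb was 1.31 in the transgenic and 1.32 in the wild-type pool, and that of Gapdh was 0.90 and 0.84. The 18 probe sets for bacterial and phage spike-in transcripts had a median log2 ratio of 0.077, between -0.40 and 0.39. The 3 control probe sets for 18S ribosomal RNA were all lower in the transgenic pool, with log2 ratios of -1.56, -1.51 and -1.35 at signals of at most 981. The ratio for Tfrc was 16.4 in the transgenic and 3.86 in the wild-type pool, from 5' signals of 31.8 and 162, which were under the 20th percentile of all signals (252). Among the sex-linked genes, Uty was at 0.45, Kdm5d at -0.62 and Eif2s3y at -0.48, with signals under the filter, and Xist was at -0.22 on the probe set that passed. The 220 X-linked genes had a median of -0.0095, at the 29.1st percentile of random lists, and the 6790 autosomal genes had a median of 0.0012. In the list of genes known to vary between C57BL/6 and DBA/2 mice, 6 were measured, with a median of -0.055 at the 35.8th percentile. Glo1, glyoxalase 1, was higher on each probe set (0.43 ± 0.08, SD, n = 3 probe sets) and Alad was at -0.77. Gabra2, Nnt, Kcnj9 and Mpdz were at -0.14, -0.062, -0.048 and 0.081, and a second Mpdz probe set gave -0.55. Klrd1, Gpnmb, Ahr, Tyrp1 and Hc were under the filter, at -1.94, -0.74, 0.32, 0.29 and 0.21.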

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

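The medians of the striatal projection neuron, interneuron and myelin lists stood apart under all 9 alternatives run on them, between 0.41 and 0.43, 0.21 and 0.24, and 0.24 and 0.31. Centring on the median shifts lists and random lists alike and could not change this. Loess and quantile normalization act by signal, on which the random lists were matched, and so were weaker checks. No paired analysis was possible because each genotype has 1 array. For the same reason no replicate could be left out. The ratio of the overexpressed gene had no alternatives, since no probe set was named for it. The numbers of higher and lower probe sets past 0.6 were 2596 and 2936 with no filter, 117 and 97 with a filter at the 75th percentile, and 231 and 240 without _s_at, _x_at and _a_at probe sets. At a size of 1.0 they were 59 and 54. The share past 0.6 was 24.4% with no filter against 6.45% with it, so the number of probe sets kept does not account for that count. The 3 scaling alternatives kept both counts within 1.5 times. They moved the median of all probe sets past the filter by under 0.1, which tests nothing, since that median was already 0.0053. The astrocyte median no longer stood apart after quantile normalization (0.060), without the 3 classes (0.059), as the mean of probe sets (0.067) or without genes that other lists hold (0.10), an alternative chosen after seeing the data. The inflammation median no longer did with no filter (-0.090), without the 3 classes (-0.19) or as the mean of probe sets (-0.094). The cortex median lay between -0.30 and -0.042 over the alternatives. It no longer stood apart without the 3 classes (-0.14) or without shared genes (-0.042), and the immediate early gene median no longer did at the 75th percentile (-0.089). The thalamus, pallidum, septum and hypothalamus median no longer did with no filter (-0.016) and changed direction at the 75th percentile (0.10). The cell cycle median came to stand apart with no filter (-0.17) and at the 75th percentile (-0.20), and the ribosomal protein median did as the mean of probe sets (0.10). The choroid plexus list, with 4 genes past the filter, moved to 2.54 at the 75th percentile and 1.43 without shared genes, and with no filter its 18 genes had a median of 0.44 that stood apart, at the 99.6th percentile. Blood cells moved to -0.49 with no filter, and the strain-variable list to 0.52 at the 75th percentile, where 1 gene was left. Without the 3 classes, Kif5c changed direction (0.090) and 7 other named genes moved by more than the within-gene SD, of which Hmgcs1, Hyou1, Pltp, Psmd11 and Suz12, under 0.6 in size, also changed direction. As the mean of probe sets 15 of 168 named genes moved so, and with the pseudocount 8 did, where Ttr (2.47) passed Cort (2.18) and Pttg1 (-2.09) passed Sc5d (-1.87). The cause was not tested for the changes in counts, in list medians or for Kif5c. Signal over background limits the genes under the filter, for which no order of ratios is claimed.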

Other observations

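The tests of explanations in this part were chosen after the result was seen, except the test on neighbouring genes, while loess and quantile normalization were alternatives planned before the data were examined. Among biology not described above, Malat1, a long noncoding RNA of the nucleus, was lower in the transgenic pool on all 5 of its probe sets, with a log2 ratio of -0.85 ± 0.28 (SD, n = 5 probe sets). Foxp1, a transcription factor of striatal projection neurons, was at -0.046 on its brightest probe set, but its 6 probe sets past the filter had a mean of 0.37 ± 0.27 (SD), and a dim one under the filter gave -2.21. Tcf7l2, a transcription factor of thalamic neurons, was higher on all 4 probe sets, between 0.58 and 2.19, with every signal under the filter. Malat1, Foxp1 and Tcf7l2 were chosen after their values were seen. Of 536 probe sets past the filter that the annotation did not list, 18 were at least 0.6 higher and 15 at least 0.6 lower.

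Genes of striatal projection neurons were higher in the transgenic pool, and the median of cortical genes was lower, with 7 of 20 members higher. Scaling or an intensity trend is argued against for the striatal list by the main comparison. There, the central range of random lists matched on signal was only -0.090 to 0.099, against a median of 0.43. Under loess and quantile normalization the median was still 0.41, whichever was lower, and stood apart. The matched lists had left little room for another outcome, so neither that median nor its percentile adds much. Less neighbouring cortex in the transgenic tissue pieces may account for part of the pattern. The cortical median without genes that other lists hold was -0.042, at the 26.1st percentile. Without _s_at, _x_at and _a_at probe sets it was -0.14 and no longer stood apart. Its lowest value over the alternatives was -0.30, so this decides nothing. Other genes tied to tissue parts also differed between these pools, in both directions, and were not part of that test. Among them were Avp (-1.30), Prkcd (1.57) and Ttr (2.54), and the myelin median was 0.26. Whole striata were dissected for these arrays, so the tissue cut of each pool and the genotype cannot be told apart with 1 pool each. An effect of the transgene on these neurons stays open and untested.

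Ttr was higher in the transgenic pool on all 3 of its probe sets, which are of the _a_at and _x_at classes. Choroid plexus carried along with the striatum is a candidate explanation. With no filter on signal, the 18 measured genes of the choroid plexus and ependyma list had a median of 0.44, at the 99.6th percentile of random lists. Without Ttr the other 17 had a median of 0.32, at the 97th percentile and just inside the range of random lists, which ended at 0.33. Only Folr1, Igf2 and Igfbp2 among them passed the filter, at 0.32, -0.13 and -0.84, so the test leaves the explanation open, as it leaves an effect of genotype.

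Pttg1 and some other genes differed far more than the rest. A chromosome segment of 1 background strain carried with the transgene might give a cluster of such genes. No window of 10 neighbouring measured genes held more than 4 past 0.6 in size, the median of shuffled gene orders. This was the highest count over all chromosomes tested and did not look near Pttg1 or the transgene, so it leaves the explanation open. The number of directly adjacent pairs past 0.6 was 34 against a median of 23 in shuffled orders, at the 98.7th percentile, and this count had no prediction. Alleles of the mixed background at different frequency in the pools could also contribute. The mean ratio in size over the 6 measured strain-variable genes was 0.27, at the 71st percentile of random lists, which is too few genes to decide, and a genotype effect stays open.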
